A study of Mus musculus with 2 samples.

How the data were processed

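H3K9ac ChIP-seq of postnatal day 0 mouse liver was analysed in 2 biological replicates of 1 group, taken from GEO's labels. Each replicate was made from pooled male and female mice, so the animal is not the unit and the spread between the replicates is that between pools. The labels name a control experiment, the mm10 assembly and a fragment size range; the peak caller, the aligner and their versions are not given in the sources used here.

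The authors deposited 4 peak lists, 1 for each replicate, 1 called on the reads of both replicates together, and 1 of replicated peaks derived from the pooled list and both replicates' lists, per the descriptions deposited with them. Column 7 of each deposited list holds a linear fold enrichment of the peak over control (a ratio), and columns 8 and 9 hold the −log10 p and −log10 q values that the authors' peak caller gave. No peak had a −log10 p under 2.00, so the deposited lists stop at p of 0.01, and many weak peaks are included. The fold enrichment is each peak's own value from the authors. It was used to describe and rank peaks within a list and to correlate matched peaks between the replicates. Ranks by fold also entered the tests of the strongest distal peaks and of fold percentiles. The files give no read counts, so the depth per replicate is unknown, no counting interval was computed, and lists of different length may differ in depth. A marked gene is one with a listed peak, and the covered length is the sum over listed peaks, so both move with how much was called.

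The peaks were compared with the GENCODE vM21 annotation and the GRCm38 (mm10) genome sequence. Over 21 chromosomes 0 peaks lay beyond a chromosome end. The 7 replicated peaks on scaffolds entered no gene result. All positions are 1-based. A protein-coding gene was called marked when a peak lay within 1 kb on either side of the TSS of any of its annotated transcripts, over 21951 genes. The covered length of a gene was the number of base pairs under peaks within 5 kb of its TSSs. Distal peaks lay more than 2.5 kb from every annotated TSS of any gene type and were assigned to the nearest protein-coding TSS within 100 kb. Joined domains bridged gaps of up to 1 kb between replicated peaks. A promoter was CpG-rich with an observed to expected CpG ratio of at least 0.6 and a GC content of at least 50% over 1 kb centred on the main TSS. Genes whose TSSs lie close together share peaks, and 3695 genes had a TSS within 2 kb of another gene's. Short reads cannot be told apart between near-identical copies such as Hba-a1 and Hba-a2 or the Serpina1 genes.

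Random placements moved the peaks 100 times within their chromosomes with bedtools shuffle, outside runs of at least 100 undetermined bases, with fixed seeds. The 24 gene lists, the tests, the thresholds and the alternatives of each result were fixed before the data were examined. Promoter marking of each list was tested against all other protein-coding genes with a two-sided Fisher's exact test. Covered length (lists with at least 5 marked members, against marked genes) and distal peaks (against all protein-coding genes) were tested with two-sided permutation tests of 10000 random lists of the same size, whose smallest possible p is 0.0001. P-values were adjusted by the Benjamini-Hochberg method over the lists of each test, with a threshold of 0.05. These tests are across genes in this tissue and say nothing of the spread across animals, and genes that share a regulator or a locus are not independent. Members of the lists Ahsp and Amy2b were not among the annotated protein-coding genes, and H19 is a non-coding gene; these were not tested.

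The genes named in the text follow a rule fixed before the data were examined. It takes the 25 longest joined domains at a TSS, with genes that share 1 domain counted as 1 entry, and the 10 distal peaks of highest fold enrichment. From each list it takes up to 4 marked members with the longest covered length and up to 4 unmarked members in alphabetical order, and of mostly unmarked lists up to 8 marked members. It adds 14 genes always reported (Alb, Afp, Hnf4a, Cyp7a1, Gata1, Hba-a1, Clec4f, Pecam1, Col1a1, Epcam, Neurod1, Myod1, Actb and Gapdh) and the first 10 list genes in alphabetical order that were marked in 1 replicate only. Gapdh was marked in both replicates. Further members were named after their values were seen to complete a group, such as the adult globin genes and the members with the most distal peaks. Some genes that the rule takes are not named in the results. Among them are the marked genes Rag1, Cd24a, Dhcr24, Fdft1, Krt23 and Prom1. The unmarked genes Adgre1 and Cd5l and the unmarked muscle, patterning and pancreas members are also left out.

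The tests were checked on simulated data with 200 lists of 20 genes per setting. For promoter marking over 21951 genes, 3.5% of null lists were called at an unadjusted p under 0.05, 98.0% of lists raised to 95 percent marked and 96.5% of lists lowered to 20 percent. For covered length over 13273 marked genes, 7.5% of null lists were called, above the nominal rate, 73.5% of lists with lengths multiplied by 1.5 and 98.5% of lists with lengths multiplied by 2. For distal peaks over 21951 genes, 4.5% of null lists were called, 94.0% of lists with 1 peak added per member and 100.0% with 2 added.

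The alternatives were the overlap that counts as shared (50% of the peak, or of both peaks), −log10 q of at least 2 or 5, equal numbers of top peaks, TSS windows of 500 bp and 2.5 kb, the gene's 5′ end only, the pooled list, each replicate alone, random lists matched on promoter CpG ratio in 10 bins, leaving out genes with close TSSs, a CpG ratio of at least 0.75, covered length within 2 kb, distal peaks over 5 kb, assignment within 50 kb, matching on the distance to neighbouring TSSs, and joining over 0 or 3 kb. Replicated peaks in both replicates' lists, matching on window length and leaving out the member with the most distal peaks were added after the data were seen. With 1 group, no contrast between conditions, paired fit or regrouping of samples was possible. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1.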

Results

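Acetylation of lysine 9 of histone H3 (H3K9ac), a histone modification found at active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the liver of newborn mice at postnatal day 0 (P0). At this age the liver holds maturing hepatocytes and is still a site of blood formation. The series had 1 group of 2 biological replicates, each made from pooled male and female animals of 1 C57BL/6N-derived stock. The design implied no contrast between conditions, so the comparisons were between the replicates, between gene groups within the tissue, and between the observed peaks and random placement. The replicate 1 list held 54574 peaks that covered 33.5 Mb, and the replicate 2 list held 65607 peaks that covered 37.1 Mb. The authors also deposited a list of 54755 peaks called on reads pooled from both replicates, and a list of 34686 replicated peaks. The files give no read counts, so the depth behind each list is unknown, and a gene without a peak is a gene at which no peak was listed at this depth.

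Promoters of 13273 of 21951 protein-coding genes (60.5%) carried a replicated peak within 1 kb of an annotated transcription start site (TSS). Among them were the albumin gene Alb, the transcription factor gene Hnf4a, the erythroid regulator Gata1 and the beta-actin gene Actb. The neuronal and muscle regulators Neurod1 and Myod1 carried no peak there in either replicate. The replicates marked 13658 and 13763 genes, a mean of 13711 ± 74.2 (SD, n = 2). Both replicates marked 13152 genes, 506 genes were marked in replicate 1 only and 611 in replicate 2 only, so that 94.9% of genes had the same state in both.

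Genes with a CpG-rich main promoter, the common promoter class of broadly used genes, were marked at 9172 of 10090 (90.9%). Genes with a CpG-poor main promoter, the class of Alb, Hnf4a and Gata1, were marked at 4101 of 11861 (34.6%). The class was taken at the main TSS, but a peak at any annotated TSS counted. The peak of a marked gene may therefore lie at another promoter than the one classed. The odds ratio was 18.9 (two-sided Fisher's exact test, p at most 1e-300), and it was 18.6 in replicate 1 and 18.0 in replicate 2. The test is across genes, which are not independent replicates.

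Of the replicated peaks, 19612 (56.5%) lay within 1 kb of a TSS, against 9.01% on average and 9.44% at most in 100 random placements. A further 5.67% lay over exons, 25.2% in introns and 12.6% between genes, where random placement gave 7.60%, 34.9% and 48.5%. The share near a TSS was 44.9% in the replicate 1 list and 39.6% in the replicate 2 list, a mean of 42.3% ± 3.76 (SD, n = 2).

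All 24 genes of secreted hepatocyte proteins had a marked promoter, among them the apolipoprotein genes Apoe and Apoc1, the transferrin gene Trf and the fetuin gene Ahsg, as did all 23 hepatocyte transcription factors, among them Hnf4a, Rxra, Ppara, Gata4 and Gata6. Of the secreted protein genes, Serpina1a was marked in replicate 1 only, and it is near-identical to neighbouring copies, so its peak is uncertain. All 18 protein-coding genes of the fetal liver list were marked, including the alpha-fetoprotein gene Afp, the growth factor gene Igf2 and the RNA-binding protein genes Igf2bp3 and Lin28b. The non-coding gene H19 of that list was marked in both replicates and was not part of the test. All 3 lists were marked more often than the other protein-coding genes (60.4%; Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists, adjusted p = 4.39e-05, 6.27e-05 and 0.00033). The full marking counts a peak at any annotated TSS. With only the 5′ end of each gene, the difference from other genes was 30.8, 38.9 and 26.6 points (Fisher's exact test, adjusted p = 0.00372, 0.000284 and 0.0499). The fetal liver list then passed only narrowly.

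All 16 genes of gluconeogenesis and glycogen metabolism were marked, among them Pcx, which encodes pyruvate carboxylase, Gpt, Slc37a4 and Aldob. So were 19 of 20 genes of fatty acid oxidation and ketogenesis, with Hmgcl, Acox1, Cpt1a and Bdh1 the most widely covered and Cyp4a10 unmarked, and all 17 genes of cholesterol synthesis and uptake, among them Hmgcr and Insig1. These lists were above other genes (Fisher's exact test, adjusted p = 0.000853, 0.0016 and 0.000525). With only the 5′ end of each gene as its TSS, the gluconeogenesis call was lost (adjusted p = 0.104, Fisher's exact test). The urea cycle and amino acid catabolism list had 12 of 14 genes marked, with Asl, Ass1, Arg1 and Hgd marked and Otc and Tdo2 unmarked, and did not pass the threshold (adjusted p = 0.0829, Fisher's exact test). It passed in replicate 2 alone (adjusted p = 0.0354), with peaks of −log10 q of at least 5 (adjusted p = 0.0403) and with only the 5′ end of each gene (adjusted p = 0.0499, all by Fisher's exact test).

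Genes of adult liver metabolism were marked at 11 of 25 promoters. The bile acid transporter gene Slc10a1, the glutamine synthetase gene Glul, Gls2, and the bile acid synthesis genes Cyp8b1, Cyp7b1 and Cyp7a1 were marked. Cyp2e1, Hal and Slco1b2 were also marked, and Ces3a, Cyp1a2, Cyp2b10 and Cyp2c29 were unmarked in the replicated list. The list did not differ from other genes (Fisher's exact test, adjusted p = 0.138). Of the acute phase and iron genes, 12 of 16 were marked, including the ferritin genes Ftl1 and Fth1, Lcn2 and the haptoglobin gene Hp, while Hamp, Orm1, Saa1 and Saa2 were unmarked (adjusted p = 0.354, Fisher's exact test).

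Erythroid genes were marked at 21 of 23 promoters (91.3%; adjusted p = 0.00349, Fisher's exact test). The erythrocyte membrane genes Ank1 and Slc4a1, the regulators Gata1, Zfpm1 and Nfe2, and the adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were marked in both replicates. The 2 unmarked members were the embryonic globin genes Hbb-bh1 and Hbb-y. Hba-a1 and Hba-a2 are near-identical, so reads cannot be placed between them with certainty. At the beta-globin cluster on chromosome 7 (mm10), replicated peaks lay at the adult genes Hbb-bt and Hbb-bs, and 11 more lay upstream of Hbb-y between positions 103858691 and 103874914, the side on which the locus control region lies. Replicate 1 had 11 and replicate 2 had 16 peaks upstream of Hbb-y.

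**Figure D1:**
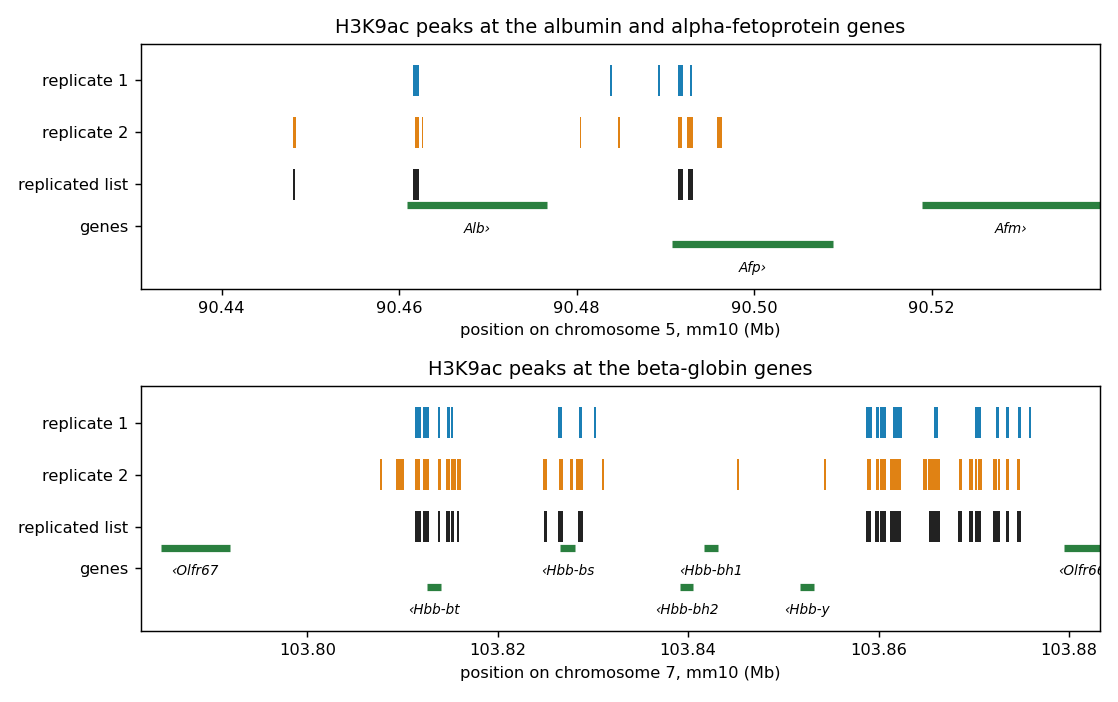
Peaks of replicate 1, replicate 2 and the replicated list at the albumin and alpha-fetoprotein genes on chromosome 5 and at the beta-globin genes on chromosome 7, with gene bodies in green, arrows for the direction of transcription, and position in Mb (mm10) on the x axis. Peaks lie at Alb and Afp and at the adult genes Hbb-bt and Hbb-bs, and 11 replicated peaks lie upstream of Hbb-y.

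At the albumin locus on chromosome 5, Alb (positions 90460897 to 90476602) had 1 replicated peak of 615 bp at positions 90461580 to 90462194, inside the gene and 125 bp from an annotated TSS. Afp (90490737 to 90508907) had replicated peaks of 530 and 626 bp, of which the first lay 156 bp from a TSS. The lengths covered within 5 kb of the TSSs were 635 ± 79.2 bp at Alb and 1310.5 ± 501.3 bp at Afp (SD, n = 2).

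Blood stem and progenitor genes were marked at 13 of 16 promoters, with Lmo2, Runx1, Meis1 and the myeloid factor Spi1 the most widely covered and Hoxa9 and Mpl unmarked in both replicates. Flt3 was marked in each replicate but not in the replicated list, and the list did not pass the threshold (adjusted p = 0.156, Fisher's exact test). Megakaryocyte and mast cell genes were marked at 2 of 12 promoters, those of the platelet glycoprotein genes Gp9 and Gp1ba, while Cpa3, Fcer1a, Gp1bb and Gp6 were unmarked, which was below other genes (adjusted p = 0.00404, Fisher's exact test). Macrophage and granulocyte genes were marked at 7 of 21 promoters (Cd68, S100a8, Prtn3, S100a9, Fcgr3, Ptprc and C1qc). Of these, Cd68 has the TSS of Eif4a1 at 1910 bp. The Kupffer cell gene Clec4f was marked in replicate 2 only. The macrophage and granulocyte list was below other genes in the replicated list (Fisher's exact test, adjusted p = 0.0204), but not in replicate 1 alone (9 of 21, adjusted p = 0.105) or replicate 2 alone (12 of 21, adjusted p = 0.713). It also lost its call with peaks called on pooled reads (Fisher's exact test, adjusted p = 0.0932), with a window of 2.5 kb (0.061) and with only the gene's 5′ end (0.0672). Lymphocyte genes were marked at 9 of 19 promoters, among them the B cell genes Cd19, Cd79a, Cd79b, Ebf1 and Vpreb1 and the T cell genes Lck and Tcf7, while Cd3g and Cd4 were unmarked (adjusted p = 0.3, Fisher's exact test). With peaks of −log10 q of at least 5 the lymphocyte list was below other genes (adjusted p = 0.0151, Fisher's exact test).

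Among other liver cells, 13 of 18 endothelial genes were marked, including Egfl7, Erg, Gpr182 and Pecam1, while Clec4g, Flt4, Oit3 and Tek were unmarked. Of the stellate cell and mesenchyme genes, 12 of 19 were marked, including Hand2, Reln, Lhx2 and Pdgfra, while Acta2, Dcn, Col3a1 and the collagen gene Col1a1 were unmarked in the replicated list. Of the bile duct genes, 9 of 14 were marked, including Hnf1b, Sox4 and Epcam, while Cftr, Krt19, Krt7 and Onecut3 were unmarked. None of these 3 lists differed from other genes (Fisher's exact test, adjusted p = 0.378, 1 and 1).

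Genes of other tissues were marked less often than other genes. Neural genes were marked at 2 of 20 promoters (Gfap and Slc17a7), and Ascl1, Dcx, Foxg1 and Gad1 were unmarked. Muscle and heart genes were marked at 3 of 20 (Ckm, Des and Actc1), of which Des is also a stellate cell gene of the list above and Ckm has the TSS of Klc3 at 672 bp. Posterior Hox and patterning genes were marked at 1 of 20 (Six1), and pancreas and gut genes at 2 of 18 (Cela1 and Lgr5). Of 1135 olfactory receptor genes, 1 was marked (Olfr56), and its TSS lies 5 bp from that of the interferon-inducible gene Ifi47. The marked members in replicates 1 and 2 were 1 and 5 for neural genes, 4 and 7 for muscle and heart genes, 1 and 3 for posterior Hox and patterning genes, 4 and 2 for pancreas and gut genes, and 2 and 6 for olfactory receptors. The muscle and heart list differed from other genes by −27.7 points in replicate 2 alone and by −45.5 points in the replicated list. All 5 lists were below other genes in the replicated list (Fisher's exact test, adjusted p = 3.28e-05, 0.000135, 3.26e-06, 8.54e-05 and, for the olfactory receptors, at most 2.4e-299). All 20 cell cycle genes and all 18 housekeeping genes were marked (Fisher's exact test, adjusted p = 0.000245 and 0.00033). Of the 24 lists, 9 were higher than other genes, 7 lower and 8 not past the threshold.

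**Figure D2:**
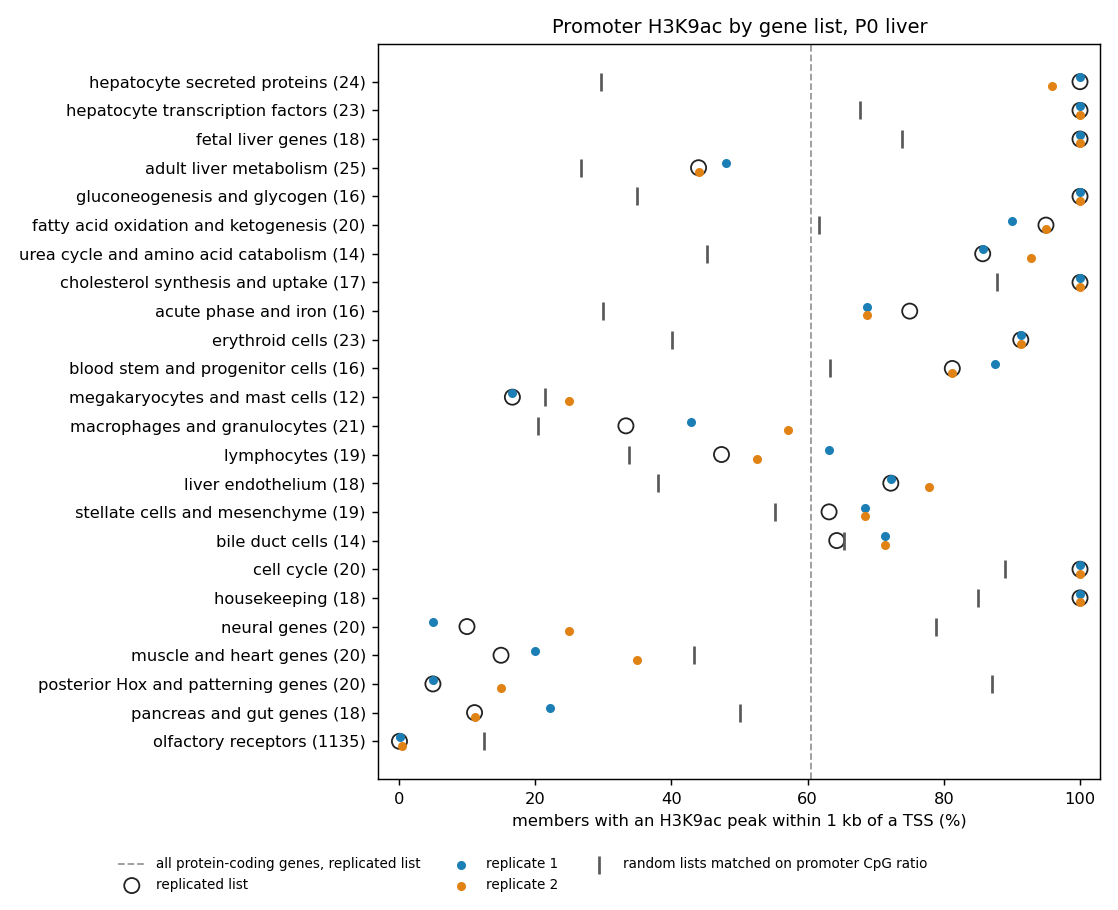
Share of each gene list's members with an H3K9ac peak within 1 kb of a TSS, in percent, for the replicated list (circles), replicate 1 (blue) and replicate 2 (orange), with the number of members in parentheses, the mean of random lists matched on CpG ratio (ticks) and the share of all protein-coding genes (60.5%, dashed line). Hepatocyte transcription factors are all marked in both replicates, and of 20 posterior Hox and patterning genes 1 and 3 are.

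Set against random lists with the same promoter CpG ratios, some liver and blood lists had a larger excess than against all other genes and others a smaller one. The excess fell from 39.6 to 32.2 points for hepatocyte transcription factors, from 39.6 to 26.1 for fetal liver genes, from 34.6 to 33.4 for fatty acid oxidation genes and from 20.8 to 17.9 for blood stem and progenitor genes. It rose from 39.6 to 64.99 points for gluconeogenesis and glycogen genes. Secreted hepatocyte protein genes, mostly CpG-poor, were all marked against 29.7% in matched lists, and erythroid genes at 91.3% against 40.1% (permutation adjusted p = 0.00024 for both, from the smallest p that the permutations can give, 0.0001). Adult liver metabolism genes were above their matched lists (11 of 25 against 26.7%, permutation adjusted p = 0.0419). So were the genes of the urea cycle (85.7% against 45.3%, 0.000436), of the acute phase (75.0% against 30.0%, 0.00024) and of the endothelium (72.2% against 38.0%, 0.0024). The matched lists were drawn from all protein-coding genes, olfactory receptors (1 of 1135 marked) and vomeronasal receptors (1 of 331) among them. Such genes lower the share in lists matched to CpG-poor genes, so the excess of CpG-poor lists may be overstated. Matching without them was not run. The CpG ratio was that of the main TSS, while a peak at any annotated TSS of a gene counted as marking. Macrophage and granulocyte genes (33.3% against 20.5%, permutation adjusted p = 0.189), lymphocyte genes (47.4% against 33.8%, 0.2) and megakaryocyte and mast cell genes (16.7% against 21.5%, 0.751) did not differ from matched lists. The calls of the cholesterol, cell cycle and housekeeping lists were lost (permutation adjusted p = 0.181, 0.181 and 0.103). All 5 lists of other tissues stayed below their matched lists. The difference grew from −50.5 to −68.9 points for neural genes and from −55.5 to −82.1 for posterior Hox and patterning genes. It shrank from −63.7 to −12.4 points for olfactory receptors, from −45.5 to −28.4 for muscle and heart genes and from −49.4 to −39.02 for pancreas and gut genes. Matched lists could hold members of the tested list itself. The 1135 olfactory receptors, with 0 CpG-rich promoters, were thus compared in part with each other, so their smaller difference is partly built in.

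The length of DNA covered by peaks around marked promoters also differed between gene groups. This length was summed over windows around all annotated TSSs of a gene. Genes with TSSs far apart therefore have more sequence that can be covered, and the length is not the breadth at 1 promoter. The median length covered within 5 kb of a TSS was 4564 bp over the 23 hepatocyte transcription factors, 4289 bp over 21 marked erythroid genes, 4113 bp over 16 gluconeogenesis and glycogen genes and 4317 bp over 13 blood stem and progenitor genes, against 2132 to 2143 bp in random lists of marked genes. Rxra had 8982.5 ± 280.7 bp, Ank1 13146.5 ± 2891.4 bp, Zfpm1 12305 ± 398.8 bp, Pcx 11080 ± 207.9 bp, Lmo2 9062 ± 355 bp and Runx1 7759 ± 101.8 bp (SD, n = 2). The permutation adjusted p was 0.0006 for the first 3 lists, from the smallest p that the permutations can give (0.0001), and 0.0018 for the stem and progenitor genes. For these the excess over random lists fell from 2174 bp to 1018 bp in replicate 1 alone (permutation adjusted p = 0.0347). Matching the random lists on window length was chosen after the data were seen. The excess was then 2454, 2173, 2024 and 2065 bp for the lists in the order above (permutation adjusted p = 0.0009, 0.0009, 0.0012 and 0.00288). These values argue against window length as the source of the excess in these lists.

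Housekeeping genes (median 3564 bp, with Hmbs, Actb, Tubb5 and Ubc the longest), cell cycle genes (3368 bp, with Rrm2, Pcna, Mcm2 and Mki67 the longest) and secreted hepatocyte protein genes (3281 bp) were also above random lists (permutation adjusted p = 0.0048, 0.00591 and 0.0048). So were the acute phase and iron list (3329.5 bp, 0.0332) and the urea cycle list (3311.5 bp, 0.0333). Marked genes of adult liver metabolism (989 bp) and of stellate cells and mesenchyme (862.5 bp) were below random lists (permutation adjusted p = 0.0434 and 0.0238). The medians of the replicates were 845 and 1151 bp for adult liver metabolism and 605 and 1017 bp for stellate cells and mesenchyme. The other 7 of the 18 lists tested did not pass the threshold, among them the fetal liver genes (2291 bp, adjusted p = 0.719, permutation). Bile duct genes passed as shorter in replicate 2 alone (permutation adjusted p = 0.0184). Within 2 kb of a TSS the calls for the secreted protein, gluconeogenesis, urea cycle and acute phase lists were lost (permutation adjusted p = 0.41, 0.491, 0.309 and 0.634), and the erythroid excess over random lists fell from 2154 to 945 bp (0.00756). The adult metabolism call was lost against lists matched on CpG ratio (0.142) and in replicate 2 alone (0.0793), and the acute phase call in replicate 2 alone (0.111, permutation).

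**Figure D3:**
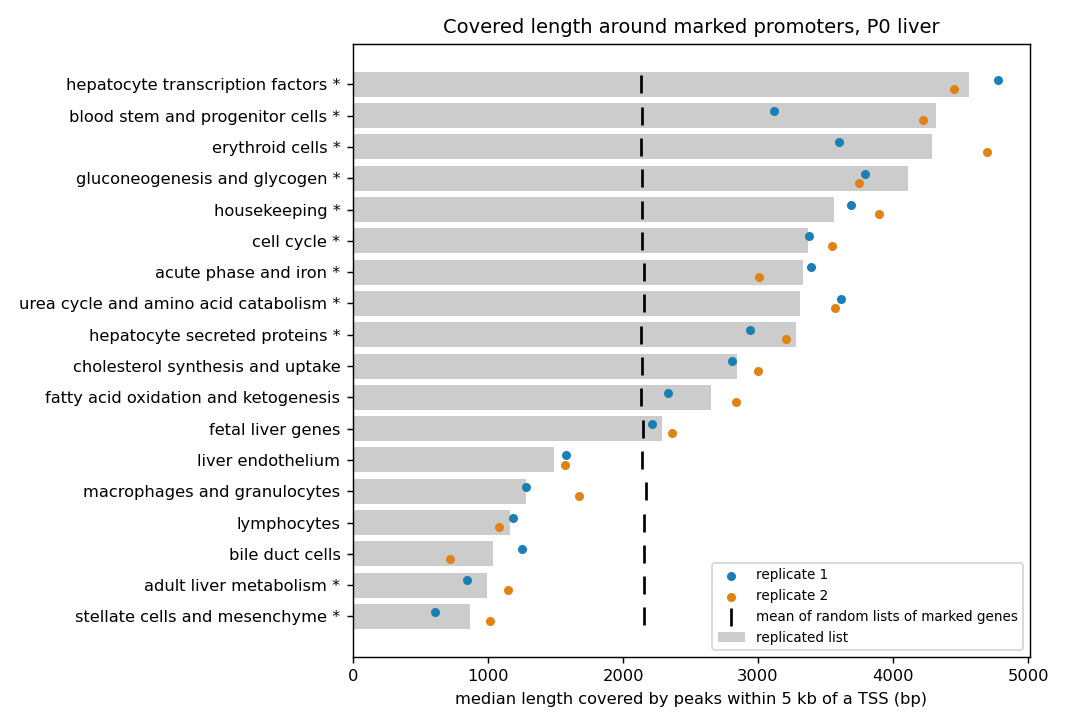
Median length covered by H3K9ac peaks within 5 kb of the TSSs of marked members, in bp, for the replicated list (bars), replicate 1 (blue) and replicate 2 (orange), with the mean of random lists of marked genes (ticks). An asterisk marks lists with a permutation adjusted p under 0.05, and the hepatocyte transcription factors are highest at 4564 bp.

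Distal peaks, more than 2.5 kb from every annotated TSS, made up 11018 of the replicated peaks (31.8%). Hepatocyte transcription factors had 80 such peaks, a mean of 3.48 per gene against 0.486 in random lists. Of these, Rxra had 24, Ppara 11, Hnf4a 8, and Cebpa and Nr1i2 had 7 each. Erythroid genes had 63, a mean of 2.74 per gene, with 23 at Zfpm1, 13 at Ank1 and 5 at Hbb-y. The nearest-TSS rule assigned only 5 of the 11 replicated peaks upstream of Hbb-y to that unmarked gene, and the rest elsewhere. Gluconeogenesis and glycogen genes had 38, a mean of 2.38 per gene, with 9 at Pck1, 8 at Pcx, 6 at Fbp1 and 5 each at G6pc and Aldob. The means of the replicate lists were 6.50 ± 0.646, 4.87 ± 0.0615 and 4.47 ± 1.10 peaks per gene (SD, n = 2). The replicate lists held more distal peaks (22272 and 30170), so these means cannot be set against 0.486. Over random lists of the same replicate the excess was 5.07, 3.95 and 2.72 in replicate 1 and 5.66, 3.54 and 3.96 in replicate 2. With replicated peaks these 3 gene lists were above random lists (permutation adjusted p = 0.0012, 0.0016 and 0.0132). The olfactory receptor genes were below (0.0176 per gene, 0.0012), and the other 20 lists did not pass the threshold. Fetal liver genes passed in replicate 2 alone (permutation adjusted p = 0.0178), and housekeeping genes passed against lists matched on the distance to neighbouring TSSs (0.0317). The smallest p that the permutations can give, 0.0001, underlies the p of the transcription factors and the olfactory receptors. With the richest member of each list left out, an alternative chosen after seeing the data, the excess over random lists was 2.06, 1.33 and 1.46 peaks per gene (adjusted p = 0.0036, 0.0328 and 0.0348, permutation). With peaks over 5 kb from a TSS the gluconeogenesis call was lost (permutation adjusted p = 0.0852), and the excess of the transcription factors fell from 2.99 to 1.84 peaks per gene.

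**Figure D4:**
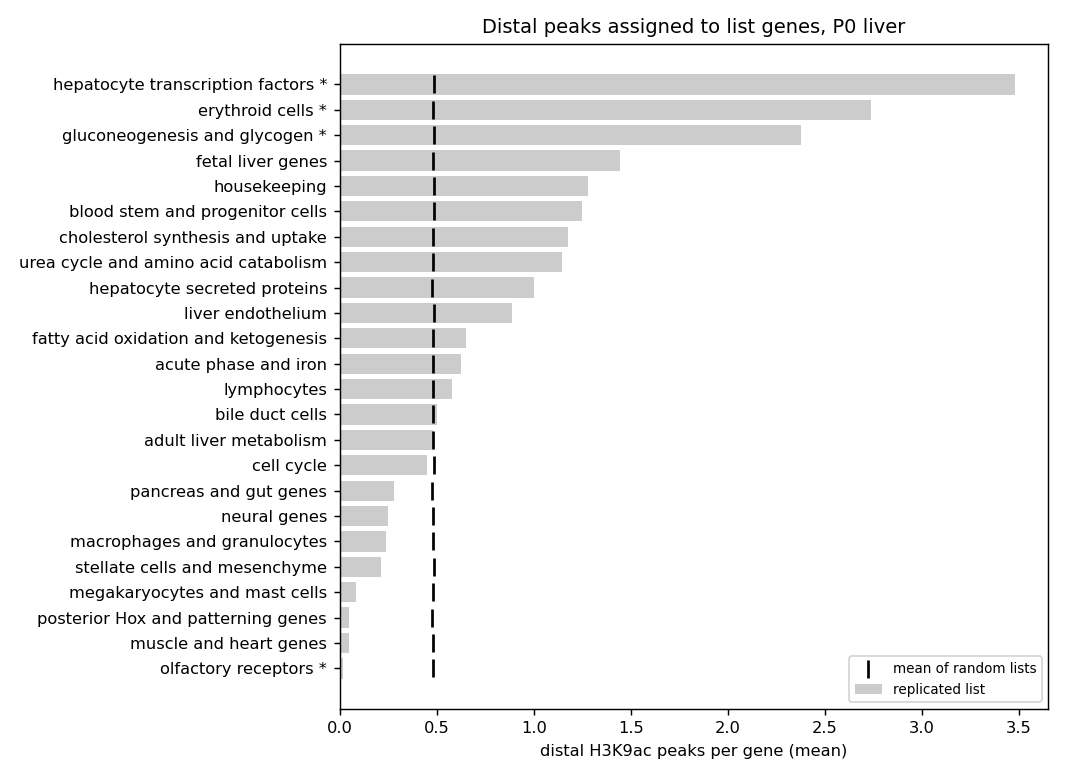
Mean number of distal H3K9ac peaks of the replicated list per gene (bars), over 2.5 kb from every TSS and assigned to the nearest protein-coding TSS within 100 kb, for each of the 24 gene lists, with the mean of random lists (ticks). An asterisk marks lists with a permutation adjusted p under 0.05, and the hepatocyte transcription factors are highest at 3.48 peaks per gene.

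Among the 10 distal peaks of highest fold enrichment, none lay nearest to a gene of the liver lists. The highest, at chromosome 1 positions 86487619 to 86489080 (fold 21.8), lay between genes, 38376 bp from the nearest protein-coding TSS, that of Ptma. The second, at chromosome 17 positions 5189370 to 5190558 (fold 21.2), lay in an intron of Arid1b, which encodes a chromatin remodelling subunit. The nearest protein-coding TSS was 149386 bp away. The others lay between genes nearest to Pum2, Chd2, Zfp292, Zfp869 and Zfp217, over exons of Pura and Sf3b5, and over an exon of the antisense gene Junos, 109167 bp from the TSS of Jun. In the RefSeq annotation of the same assembly a TSS lay inside 3 of these 10 peaks, those at Pura, Zfp869 and Sf3b5. A RefSeq TSS lay 33726 bp from the Arid1b peak. All 10 overlapped peaks in both replicates' lists.

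The longest joined domains, replicated peaks joined over gaps of up to 1 kb that overlapped a TSS window, lay at Irf2bp2 (chromosome 8, 126582820 to 126598163, 15344 bp), at Josd1 and Gtpbp1 (15071 bp) and at the gene-dense locus of Junb, Prdx2, Rnaseh2a and Gm49661 (14884 bp). Gpr146 (14793 bp), the erythrocyte membrane gene Epb41 with Gm10300 (14338 bp), the syndecan gene Sdc4 (12834 bp) and the erythroid factor gene Klf3 (12681 bp) followed. Of the gene lists, the 25 longest held Rxra (11909 bp), the apolipoprotein genes Apoe and Apoc1 with Tomm40 (11634 bp) and the erythroid gene Tspan33 (11164 bp), and no test was made of whether any list was over-represented. The rest of the 25 were at Cyb5a (11667 bp), Apoc2 with Apoc4 and Gm44805 (11274 bp), the insulin receptor substrate gene Irs2 (11104 bp), Tst with Mpst, Cd82, Hs6st1, a histone cluster (Hist1h2ah, Hist1h2bk, Hist1h4i, Hist1h2ag and Hist1h2bj), Zbtb7b, Mrm1 with Dhrs11, Tnrc18, Gse1, B4galt1, Gnai2, Tbc1d24 with Ntn3, and Ampd3. Peaks of the replicates covered 12050.5 ± 67.2 bp of the Irf2bp2 domain and 6286.5 ± 1439 bp of the Ampd3 domain (SD, n = 2). The ranking depended on the joining. Without joining, only the Irs2 and the Tst and Mpst domains stayed among the 25 longest, led by Irs2 (10545 bp), E2f2 (9299 bp) and Nfe2 (9265 bp). With gaps of up to 3 kb bridged only the Junb, Gse1 and Epb41 domains stayed, and Ank1 was longest (31605 bp).

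Both replicates placed most strong peaks at the same sites. Of the replicate 1 peaks, 33293 (61.01%) overlapped a replicate 2 peak by at least 1 bp, against 2.99% on average and 3.19% at most in 100 random placements. Of the replicate 2 peaks, 33145 (50.5%) overlapped a replicate 1 peak, against 2.5002% on average and 2.70% at most. The random placements took no account of promoters, where 44.9% of replicate 1 and 39.6% of replicate 2 peaks lay. Lists that gather at promoters overlap more than such placements, so this comparison does not measure how well the replicates match. Across 29373 matched peaks Spearman's rho of the authors' fold enrichment was 0.848 and Pearson's r of its log2 was 0.921; this is across peaks, which are not independent replicates. Peaks in 1 list only were short and weak. The 32462 peaks in the replicate 2 list only had a median length of 234 bp and a median −log10 q of 1.78, against 567 bp and 5.83 for the shared ones. With a −log10 q of at least 5 in both lists, 81.6% of replicate 1 peaks and 85.4% of replicate 2 peaks overlapped.

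Genes with a promoter peak in 1 replicate only included several of non-hepatocyte cells. Among the 430 protein-coding list genes other than olfactory receptors, 41 were marked in 1 replicate only, 16 in replicate 1 and 25 in replicate 2. In alphabetical order the first 10 were the complement genes C1qa, C1qb and C1qc, the lymphocyte genes Cd2 and Cd3e, Clec4f and the endothelial gene Clec4g, the collagen genes Col1a1 and Col3a1, and the macrophage receptor gene Csf1r. C1qa, C1qc, Cd2, Cd3e and Col1a1 were marked in replicate 1 and the other 5 in replicate 2. Of the 41 genes, 10 were marked in the replicated list. Of the other genes named above as unmarked, Cyp1a2, Cyp2b10 and Krt19 were marked in replicate 1 only, and Otc, Gp1bb, Krt7 and Foxg1 in replicate 2 only.

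The replicated list was a subset of the pooled list. It held 34686 of 54755 pooled peaks (63.3%), and those left out had a median fold of 2.80 and a median length of 235 bp, against 4.29 and 626 bp for those held. Of the pooled peaks with a −log10 q of at least 5, 98.6% were in the replicated list. Of the replicated peaks, 29064 (83.8%) overlapped a peak in both replicates' lists, 2466 in replicate 1 only, 2960 in replicate 2 only and 196 in neither.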

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

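No test in this part was chosen after its result was seen. The replicated list held 7 peaks on scaffolds not placed in the chromosome sequences, which entered no gene result and stood out as signal outside the comparisons. Of these, 2 lay on a scaffold assigned to chromosome 4 (highest fold 8.87), 3 on a scaffold assigned to chromosome X (highest fold 7.996) and 2 on an unplaced scaffold (highest fold 2.61 with a −log10 q of up to 48.6). Each replicate's list held 7 peaks on scaffolds. No explanation for these peaks was tested.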

How the results depend on the processing

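Of 552 alternative values, 479 kept their direction and side of the threshold if tested, stayed within the replicate spread if untested or within 1.5 times if a count, 23 moved and 22 changed direction. In all, 11 passed the threshold where the main value did not, and 19 lost it, of which 1 each also changed direction. The rank correlation and the replicated share of pooled peaks have no value per replicate, and every change in them was counted as moved. The peaks in both replicates' lists, matching on window length and leaving out the richest member were chosen after seeing the data. No paired analysis was possible because the series has 1 group. The causes were not tested unless stated. Depth is unknown, so weak peaks limit every count.

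The overlap of replicate 1 peaks was 52.9% with 50% of the peak covered, 40.6% with 50% of both peaks shared and 81.6% at a −log10 q of at least 5; for replicate 2 peaks it was 43.02%, 33.8% and 85.4%, and 65.0% at a −log10 q of at least 2. The rank correlation was 0.863 by −log10 p, 0.903 with 50% of both peaks shared and 0.903 at a −log10 q of at least 5. At that threshold 98.6% of pooled peaks were replicated. The share of peaks near a TSS was 51.4% with 500 bp, 68.2% with 2.5 kb, 45.7% with the 5′ end only, 73.6% at a −log10 q of at least 5, 43.98% in the pooled list, 62.3% for peaks in both lists, and 39.6% to 44.9% in the replicates alone. The number of marked genes stayed between 12367 and 13819 in all alternatives.

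Differences in promoter marking below are in percentage points from other genes or from matched lists. For macrophages and granulocytes the difference was −23.5 with 2.5 kb, −23.5 with the 5′ end only, −20.1 in the pooled list, −19.4 to −5.56 in the replicates alone and 12.9 against CpG-matched lists. With the 5′ end only it was 24.5 for gluconeogenesis and 29.0 for the urea cycle, which passed. At a −log10 q of at least 5 it was 29.4 for the urea cycle, −30.0 for lymphocytes, −0.784 for endothelium and −19.5 for stellate cells. The replicates alone gave 23.5 to 30.2 for the urea cycle and −10.1 to 0.938 for lymphocytes. Peaks in both lists gave −1.22 for stellate cells. Against CpG-matched lists it was 17.3 for adult metabolism, 40.5 for the urea cycle, 44.9994 for the acute phase, 34.2 for endothelium, 13.5 for lymphocytes, 12.2 for cholesterol, 11.02 for the cell cycle, 15.0 for housekeeping, −4.81 for megakaryocytes and mast cells and −1.003 for bile duct.

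For covered length within 2 kb the excess was 266 bp for secreted proteins, 263 bp for gluconeogenesis, 483 bp for the urea cycle and 197 bp for the acute phase, and 5 lists were higher. Against CpG-matched lists adult metabolism differed by −871 bp, and 1 list was lower. The replicates alone gave −1216 to −988 bp for adult metabolism, 864 to 1501 bp for the acute phase and −1446 to −1016 bp for bile duct, which passed in replicate 2.

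For distal peaks per gene, a distance of over 5 kb gave 0.921 for gluconeogenesis and 0.0295 for adult metabolism, and assignment within 50 kb gave 0.039 for adult metabolism and −0.0216 for bile duct. Matching on neighbouring TSSs gave −0.183 for bile duct, 0.11 for the cell cycle and 0.958 for housekeeping, which passed. The replicates alone gave 1.70 to 2.65 for fetal liver genes (passing in replicate 2), −0.221 to −0.184 for bile duct, −0.0643 to 0.0339 for adult metabolism, −0.233 to 0.0187 for lymphocytes and −0.0443 to 0.0759 for the cell cycle. Without the richest member it was −0.00583 for fatty acid oxidation, −0.0124 for the acute phase, −0.314 for lymphocytes and −0.094 for bile duct. Of the 25 longest domains, 2 stayed without joining and 3 with gaps of up to 3 kb, by construction of the joining.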

Other observations

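The gene families below, the sign test, the match of fold percentiles and the CpG test of distal peaks were chosen after the results were seen. Families were drawn by symbol, 21 in all, and 6 were marked more often and 5 less often than lists matched on promoter CpG ratio (adjusted p under 0.05), while 7 were above and 9 below all other genes. All 78 mitochondrial ribosomal protein genes, all 46 complex I genes and all 34 aminoacyl-tRNA synthetase genes were marked in both replicates (permutation adjusted p = 0.00525, 0.0078 and 0.0155 against matched lists). Zinc finger Zfp genes were marked at 306 of 365 (83.8% against 69.0%), coagulation factor genes at 7 of 10 (F2, F5, F7, F8, F10, F11 and F12, but not F9, F13a1 or F13b; matched 29.3%) and cytochrome P450 genes at 34 of 98 (34.7% against 24.98%). Against all other genes the P450 genes were below (60.6%, adjusted p = 6.46e-07, Fisher's exact test) and the coagulation factor genes did not differ (p = 0.749, Fisher's exact test). None of 22 major urinary protein genes was marked in either replicate (matched lists 11.5%, permutation adjusted p = 0.129). Whether reads can be placed uniquely among these gene copies was not tested, so a missing peak need not mean missing acetylation.

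Hox genes were marked at 9 of 39 promoters against 81.6% in matched lists. The 9 were Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxa7, Hoxb2, Hoxb3, Hoxb4 and Hoxb5, all in the HoxA and HoxB clusters, and all were marked in both replicates. Clustered protocadherin genes were marked at 2 of 57 (matched 66.6%), keratin and keratin-associated genes at 7 of 110 (30.6%), defensin genes at 1 of 64 (12.9%) and vomeronasal receptor genes at 1 of 331 (11.2%). The permutation adjusted p was 0.00042 for all of these but the defensins (0.00945), from the smallest p that permutations can give (0.0001). Matched lists of the families were drawn from all protein-coding genes. They could hold members of the same family and the rarely marked olfactory receptors. Among non-coding genes, 752 of 5854 long intergenic genes (12.8%) had a marked promoter, and of those over 1 kb from every coding TSS 468 of 5461 (8.57%).

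The replicate 2 list was longer than the replicate 1 list and a smaller share of it was shared. Of the peaks in replicate 2 only, 17.9% lay within 1 kb of a TSS, above the highest of 100 random placements (7.63%). This argues against background placed without regard to promoters as the source of all of them. It cannot exclude background that itself gathers near promoters, or that many of these peaks are background. Of the peaks in replicate 1 only, 20.6% lay there, so the share does not tell why the replicate 2 list was longer. Weak peaks near the calling threshold are a possible explanation, since the surplus of replicate 2 lay among them. At a −log10 q of at least 2 the replicate 2 list held 39886 peaks and the replicate 1 list 42164. At a −log10 q of at least 5 they held 18754 and 19871. Peaks in 1 list only were weak in either replicate, with 2.28% in replicate 2 and 4.29% in replicate 1 at a −log10 q of at least 5. Why more weak peaks were listed in replicate 2 was not tested. A different cell mix in the pools stays open. Genes marked in replicate 2 only were over-represented among macrophage and granulocyte genes (6 of 21, adjusted p = 0.000172, Fisher's exact test over 10 lists), but 3 were marked in replicate 1 only, and 6 against 3 does not separate the replicates (exact sign test, p = 0.508).

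Macrophage, granulocyte, megakaryocyte and mast cell genes together were marked less often than other genes in the replicated list (9 of 33, 27.3% against 60.5%), with 11 of 33 marked in replicate 1 and 15 of 33 in replicate 2. CpG-poor promoters are a candidate explanation: against lists matched on CpG ratio the difference was 6.39 points in the other direction (permutation p = 0.36), and the median CpG ratio was 0.149 against 0.571 over all genes. These matched lists drew on all protein-coding genes, the rarely marked olfactory receptors included. A small number of these cells stays open and untested by cell counts. The 9 marked members had a median fold at percentile 9.65 among marked genes, but CpG-matched marked genes had 21.6, and the difference did not pass the threshold (permutation p = 0.187).

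Some strong H3K9ac peaks lay far from every GENCODE TSS. Promoters missing from that annotation may account for part of them: of the top 10% of distal peaks by fold, 17.0% lay within 1 kb of a RefSeq TSS against 7.09% of the others (Fisher's exact test, p = 9.59e-25), and 14.8% against 1.79% were CpG-rich. That leaves most of them without such a TSS. Whether they are distal elements of liver and erythroid genes stays open: the nearest gene was in those lists for 2.82% of the top peaks and 2.73% of the others (Fisher's exact test, p = 0.846).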
